A study of Mus musculus with 3 samples.

How the data were processed

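RNA-seq of CD8+ T cells from mouse spleen gave 1 library for each of 3 groups: naive, central memory and effector memory. The deposited table holds whole-number read counts per gene symbol, with 1 column per group. The columns TN, TCM and TEM were taken from their abbreviations as naive, central memory and effector memory. The submitters' processing notes name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 build. The annotation, strandedness and treatment of multi-mapping reads are not given in the sources used here, nor is the number of animals behind a library.

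The table has 25638 gene names, of which 16331 had a count in at least 1 library and 9307 were at 0 in all 3. Totals were 26876909 counts for naive, 35846315 for central memory and 33087462 for effector memory. Gene names were matched to GENCODE M21, where 98.7% were found. Some genes had no entry in the table and were not analysed here: the constant regions of the T cell receptor, several immunoglobulin constant regions, and the markers Scart2 and Ahsp. Genes with near-identical copies were kept.

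Counts were scaled by effective library size (CPM) with trimmed mean of M values (TMM) factors from edgeR 4.0.16 in R 4.3.3, at 1.04 for naive, 0.999 for central memory and 0.967 for effector memory. Each comparison was the ratio of CPM between 2 libraries, with the 95% exact (Clopper-Pearson) counting interval of the ratio. A gene was called higher or lower when it had at least 5 CPM in the higher library, a ratio of at least 2 and an interval excluding 1. This is a rule of size and not a test, since each group has 1 library and no p-value across genes was computed. Where a library had 0 counts, the ratio was computed against 3 counts and is given as a bound, written as at least. The lower end of the 95% counting interval lies below such a bound. For Ifitm1 in effector memory against naive it was 7873-fold, beside at least 9681-fold. The comparisons were central memory against naive, effector memory against naive, and effector memory against central memory. These rules, the gene lists and the alternatives were set before the data were examined, except for the choices named as made later.

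Genes were named by a rule. In each comparison it took, among called genes with at least 20 CPM in the higher library, the 10 higher and the 10 lower whose interval bound nearest a ratio of 1 was most extreme. Unnamed gene models and receptor or immunoglobulin segments were left out. From each list it took up to 4 called members with the largest differences, and Cd8a, Cd3e, Cd4 and Cd44 were named throughout. Some genes that the rule takes are not given. Receptor variable segments, Gapdh, Mki67 in effector memory against naive, and members named because they entered or left a list under another setting fall outside the rule and were chosen after their values were seen.

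There were 37 gene lists, of which 30 had at least 5 members with 5 CPM or more in at least 1 library. The median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when it lay outside the central 95% of them. Genes at 0 in 1 library of a pair entered the medians at their bound, and genes at 0 in both were left out of them. The position of central memory was its log2 CPM on the line from naive to effector memory, over genes at least 4-fold apart between these. The covariance and correlation of the differences from naive were set beside 100 simulated sets of unchanged Poisson counts that share a naive library. Their overlap of calls is not used, because counting error alone gives the rule no calls to share. Lists of hypoxia response, amino acid transport, nucleolar and interferon sensor genes were added after the data were examined.

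The calling rule was tested on simulated data with the depths of effector memory and naive, on the 25638 genes of the table. Only 200 genes were changed there, equally up and down. They were drawn from genes with a mean of at least 10 CPM, above the 5 CPM limit of the rule. The share of changed genes called near that limit was therefore not tested. In the real comparison 37.9% of genes at 5 CPM were called, so error of the scaling at that extent was not tested. With Poisson counts, 100 of 100 genes set 3-fold apart and 100 of 100 set 6-fold apart were called, and 0 of 9498 unchanged genes. With an added coefficient of variation of 0.2 between libraries, 92 of 100 and 100 of 100 were called, and 186 of 9555 unchanged genes (1.95%). Alternatives tried were total counts, DESeq2 1.42.0 size factors, upper quartile factors, other minimum levels, other ratios, 10 expression bins and log2(CPM + 1). Trends with GC content and transcript length were removed as a check, with values for 99.2% of the genes. Other computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.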

Results

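The series holds RNA-seq read counts for CD8+ T cells from the spleens of wild-type, untreated mice, with 3 libraries in 3 groups: naive cells, central memory cells and effector memory cells. Naive T cells have not met their antigen, central memory T cells keep the receptors for entry into lymph nodes, and effector memory T cells are the antigen-experienced cells that patrol tissues and blood. Each group has 1 library, so none of the differences has a replicate check, and each comparison is between single libraries. The totals were 26876909 counts for naive, 35846315 for central memory and 33087462 for effector memory. A count of 0 allowed up to 0.108, 0.0837 and 0.0938 normalised CPM (counts scaled by effective library size) in these libraries (3 counts each). Of the 16331 genes with a count in any library, 10226 reached 5 CPM in at least 1. Intervals are 95% counting intervals of a ratio between libraries; they and the floors cover counting error only.

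T cell genes were present in all 3 libraries. Cd8a, the CD8 alpha chain (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173), stood at 1868 CPM in naive, 1063 in central memory and 408 in effector memory. Cd3e, a signalling chain of the T cell receptor complex (ENSMUSG00000032093.7, chromosome 9, 44998740 to 45009627), stood at 395, 418 and 335 CPM. Cd4 was low throughout, at 2.12, 0.251 and 0.281 CPM. Cd44, the adhesion receptor used to define antigen-experienced T cells (ENSMUSG00000005087.17, chromosome 2, 102811141 to 102901665), was at 2.95, 45.8 and 113 CPM. Coordinates are those of GENCODE M21 on the mouse build GRCm38.

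The libraries also differed in the T cell receptor genes they carried, a feature examined after the values were seen. Trbv12-1, a receptor beta chain variable segment (ENSMUSG00000095574.2, chromosome 6, 41113550 to 41114067), made up 7.13% of all Trbv counts in naive (1107 of 15526, exact 95% binomial interval 6.73% to 7.55%). It made up 99.6% in central memory (23853 of 23937, interval 99.57% to 99.72%) and 98.4% in effector memory (5007 of 5090, interval 97.98% to 98.70%). The naive library had 19 Trbv segments at 5 CPM or more, and each memory library had 1. Every comparison of a memory library with naive is therefore also one between libraries of different receptor use.

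**Figure D1:**
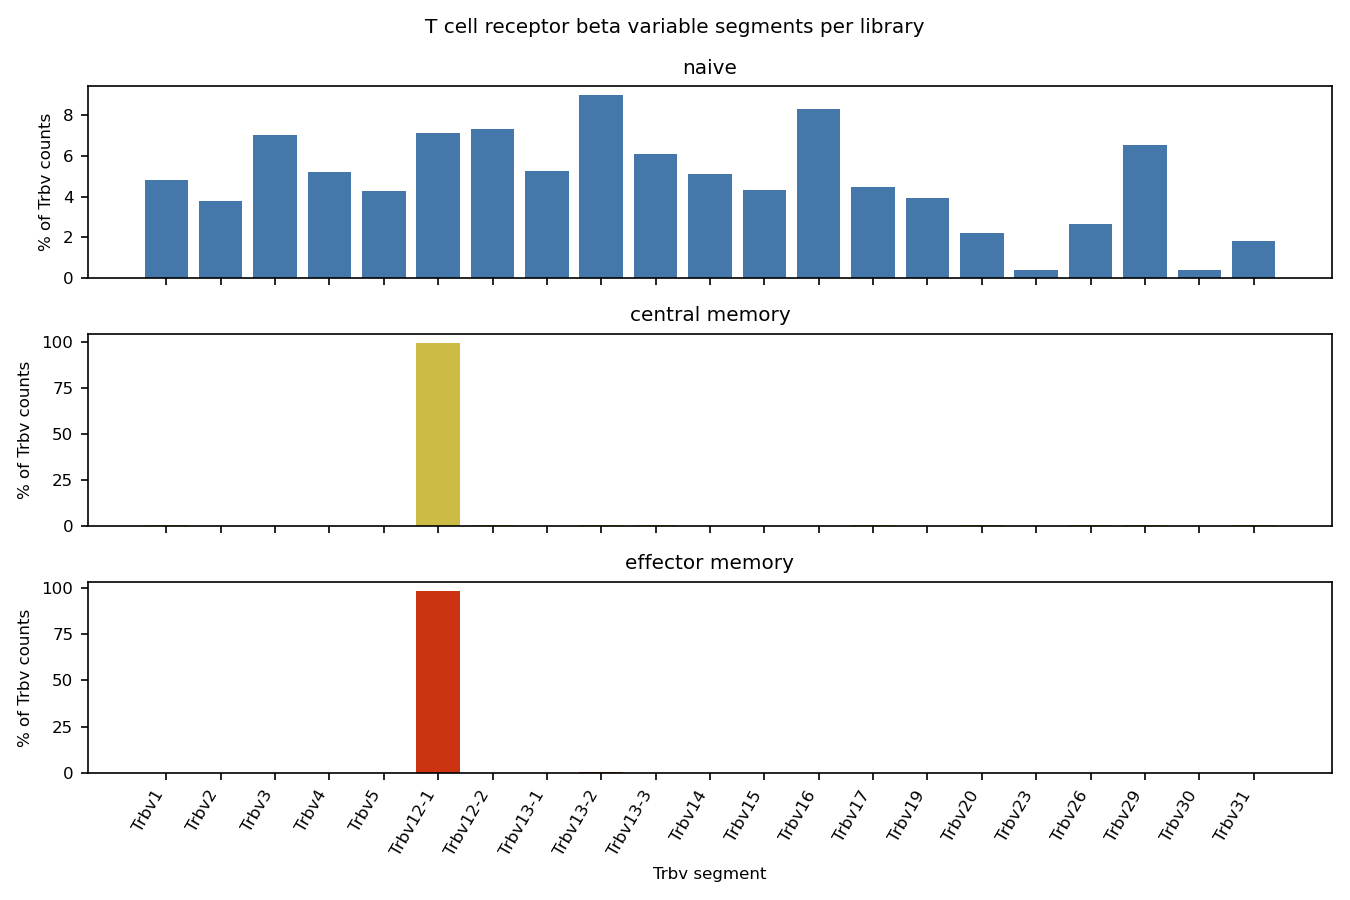
Share of all Trbv counts (percent, vertical axis, separate scale per panel) held by each T cell receptor beta variable segment with at least 1 CPM in any library, with 1 panel per library. Trbv12-1 holds 7.13% in naive, 99.6% in central memory and 98.4% in effector memory.

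The first comparison asked how the central memory library differed from naive. All 20 measured mitosis genes and 10 of 11 killer lectin-like and NK-type receptors were higher in central memory, while 14 of 23 interferon-stimulated genes and the gut homing receptor Ccr9 were lower. Osbpl3, an oxysterol-binding protein relative (ENSMUSG00000029822.15, chromosome 6, 50293330 to 50456201), was 1249-fold higher (interval 488 to 4585), at 0.144 CPM in naive and 179.5 in central memory. Ccr9 (ENSMUSG00000029530.16, chromosome 9, 123678439 to 123784330) was 561-fold lower (interval 355 to 947), at 282 and 0.502 CPM. Of 9737 genes with at least 5 CPM in either library, 1092 were higher and 499 lower by at least 2-fold with an interval excluding 1, and 509 and 193 of these differed by at least 4-fold.

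Of 11 measured chemokine and chemokine receptor genes, 7 were higher and 2 lower (median log2 ratio 2.19, percentile 99.98). Ccr2 was 476-fold higher (interval 219 to 1299), and the chemokine Ccl5 was 378-fold higher (interval 239 to 637) at 244 CPM. The killer lectin-like and NK-type receptor list held 19 genes, and 10 of its 11 measured members were higher (median log2 ratio 6.07, percentile 100). Members near 0 in naive count as measured only where a memory library reached 5 CPM, which favours calls of higher. Klrg1 was among the members below 5 CPM in all 3 libraries. Klrc1, which encodes NKG2A, had 2 counts in naive and was 898-fold higher (interval 248 to 7416). Klrb1c stood at 0.216 and 32.97 CPM, and Ncr1, an activating receptor typical of natural killer cells, at 0 and 12.2 CPM. The list of NK cell markers shares some of these genes and the same filter. It had 6 of 7 measured members higher (median log2 ratio 4.79, percentile 99.95), among them Gzma and Fcer1g. Whether these transcripts came from NK cells in the library or from the CD8+ T cells was not tested.

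Of 14 cytotoxic effectors, 5 were higher and 9 passed in neither direction (median log2 ratio 0.74, percentile 99.99). The death ligand Fasl had no count in naive and was at least 409.6-fold higher, Gzmb was 264-fold higher (interval 163 to 463) and Gzma was 158-fold higher (interval 95.8 to 283). Gzmd, another granzyme, was at least 352-fold higher. Of 12 effector transcription factors, 7 were higher (median log2 ratio 1.80, percentile 100), including Bhlhe40, 36.7-fold higher, and Tbx21, which encodes T-bet, 21.1-fold higher. The memory phenotype list had 11 of 15 members higher (median log2 ratio 2.10, percentile 100), with Cxcr3 at 5.93 and 209 CPM and Cd44 15.5-fold higher (interval 12.4 to 19.6). Of 14 measured members of the inhibitory receptor and exhaustion list, 9 were higher and 2 lower (median log2 ratio 2.86, percentile 100). Lag3 was 367-fold higher, Tigit 71.1-fold higher and Pdcd1, which encodes PD-1, 38.4-fold higher. The list of cytokine receptors had 7 of 21 higher and 3 lower (median log2 ratio 0.58, percentile 99.96), led by Il2ra at 0.719 and 48.6 CPM.

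Of 20 migration, S100 and annexin genes, 11 were higher in central memory, none was lower and 9 passed in neither direction (median log2 ratio 1.27, percentile 100). S100a6 was 582-fold higher (interval 249 to 1794) and the integrin Itgax was 321-fold higher (interval 174 to 669.6). Spp1, which encodes the secreted protein osteopontin, and Mme, a membrane peptidase, had no count in naive and were at least 412-fold higher and at least 306-fold higher. All 20 mitosis genes were higher (median log2 ratio 5.78, percentile 100), among them Ccna2, 145-fold higher, and Mki67, at 2.62 and 301 CPM. Of 20 DNA replication genes, 15 were higher (median log2 ratio 1.36, percentile 100), with Rrm2 79.8-fold higher.

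The naive and lymphoid homing list was lower as a whole in central memory, with 6 of 16 members passing downward and none upward (median log2 ratio -0.81, percentile 0). Besides Ccr9, Igfbp4 was 17.7-fold lower (interval 16.7 to 18.7) and Sox4 was 7.54-fold lower (interval 5.39 to 10.8). Of 23 interferon-stimulated genes, 14 were lower and none higher (median log2 ratio -1.39, percentile 0). Oasl2 was 265-fold lower (interval 121 to 723), Ifit3 18.00-fold lower (interval 15.2 to 21.5) and Rsad2, the antiviral protein viperin, 28.7-fold lower (interval 20.4 to 41.8). Oas2 and Oasl1, also of the interferon-induced oligoadenylate synthetase family, were 243-fold lower and 100.4-fold lower, and Tlr7, a sensor of single-stranded RNA, was 67.5-fold lower. Of 15 immediate early and heat shock genes, 7 were lower and 2 higher (median log2 ratio -0.97, percentile 0), with Fos 198-fold lower (interval 131 to 317). Other genes named by the rule were Zfp990, 394-fold lower, Ramp1, 159-fold lower, Tspan9, 126-fold lower, and Tmie, 62.2-fold lower.

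The list of T cell receptor and CD8 identity genes had no member past the rule (median log2 ratio -0.01, percentile 25.7), nor had the ribosomal proteins (median log2 ratio 0.23, percentile 95.3) or MHC class I presentation genes (median log2 ratio -0.10, percentile 8.63). The 10 measured mitochondrially encoded genes had 4 lower and none higher (median log2 ratio -0.98, percentile 0), with mt-Nd1 2.24-fold lower. Glycolysis genes had 4 of 18 higher (median log2 ratio 0.66, percentile 100), cholesterol synthesis genes 5 of 18 (median log2 ratio 0.62, percentile 99.9), fatty acid oxidation genes 2 of 16 (median log2 ratio 0.50, percentile 99.3; within the random range at a minimum of 1 CPM) and nuclear oxidative phosphorylation genes 2 of 24 (median log2 ratio 0.41, percentile 99.8). The BCL2 family list had 6 of 15 higher and 2 lower (median log2 ratio 0.92, percentile 99.93), with Bcl2l1, an inhibitor of cell death, 5.56-fold higher. Costimulatory receptors had 4 of 13 higher (median log2 ratio 0.47, percentile 98.03), with Slamf7 34.5-fold higher, and the list lay within the random range at a minimum of 20 CPM. Cytokine genes had 2 of 8 higher (median log2 ratio 0.72, percentile 97.04). The progenitor and memory transcription factors had 2 higher and 2 lower of 12, with a median log2 ratio of -0.38 at percentile 0.180 and a mean of 0.07. Myb was 9.09-fold higher and Klf3 2.86-fold lower. Tissue residency genes went both ways, 5 higher and 5 lower of 13, with a median of -0.68 (percentile 0.0850) and a mean of 0.34; at a minimum of 20 CPM the median changed sign.

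**Figure D2:**
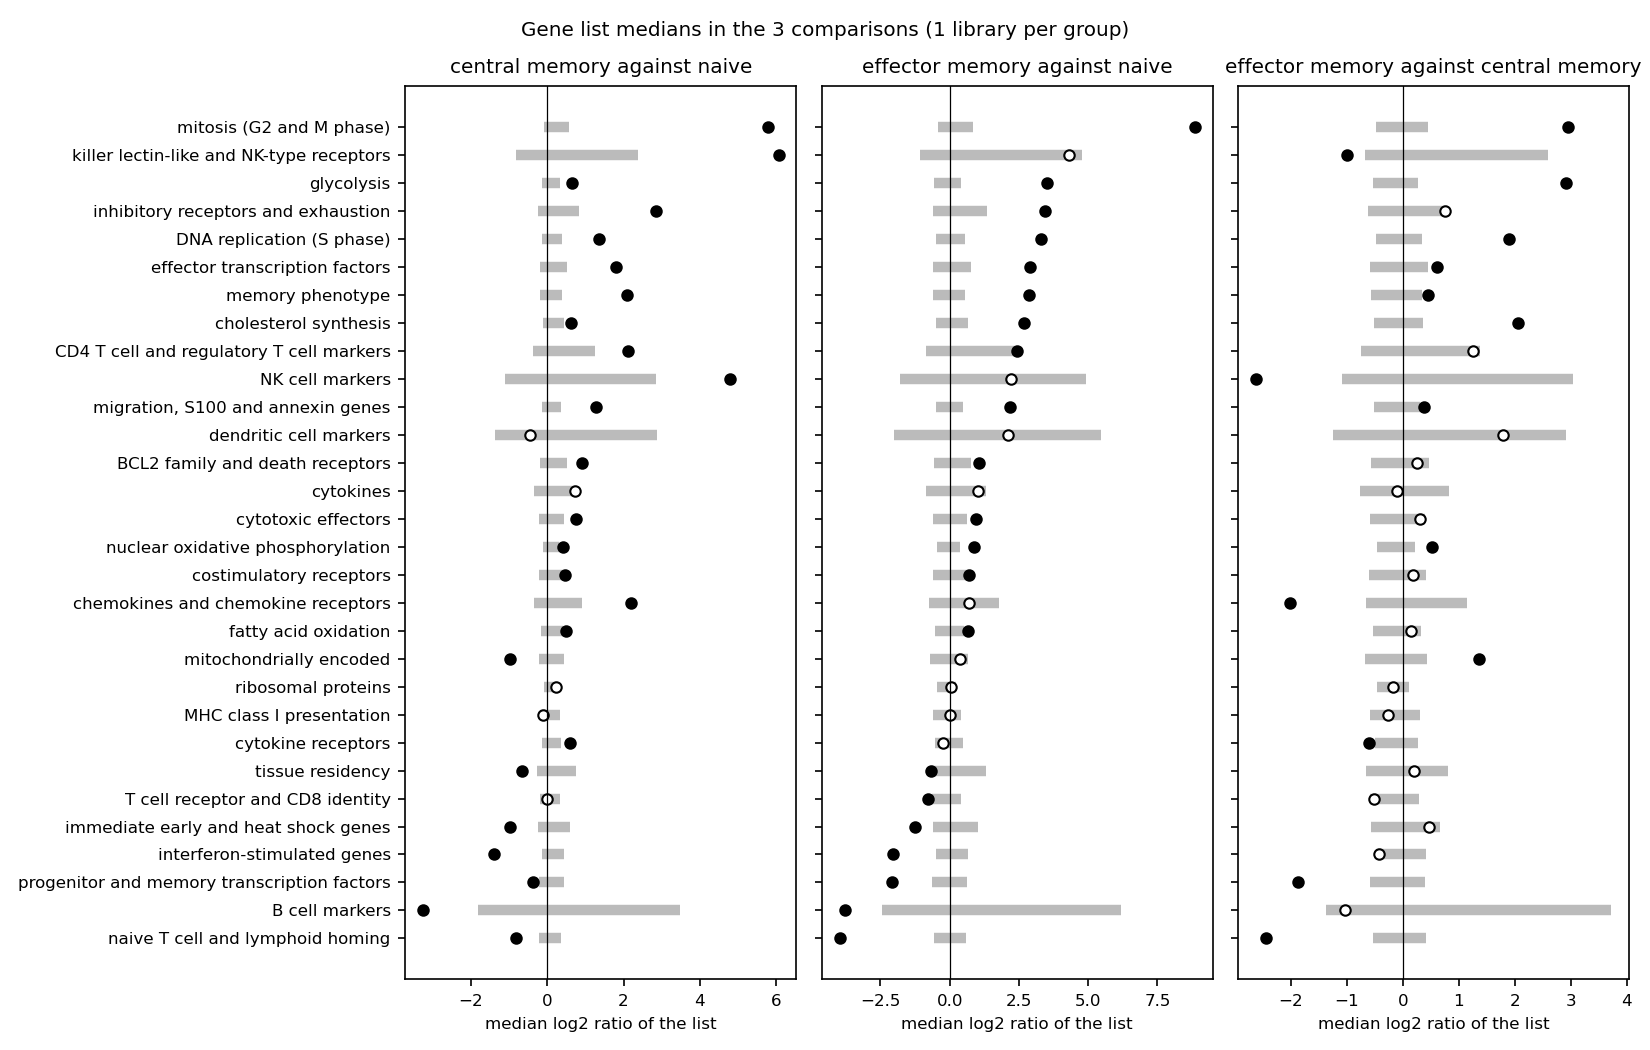
Median log2 ratio (horizontal axis, separate scale per panel) of each gene list with at least 5 measured members, with 1 panel per comparison; grey bars show the central 95% of 10000 random lists matched on mean expression. Filled points lie outside that range and open points inside; the mitosis list stands at 5.78, 8.86 and 2.95 from left to right.

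The second comparison set effector memory against naive and gave the largest number of differing genes of the 3 comparisons. All 20 measured mitosis genes and 17 of 18 glycolysis genes were higher in the effector memory library, and 15 of 16 naive and lymphoid homing genes were lower. Gzmb, the main granzyme of cytotoxic T cells (ENSMUSG00000015437.5, chromosome 14, 56258838 to 56262260), was 10985-fold higher (interval 6764 to 19219), at 0.575 CPM in naive and 6317 in effector memory. Il6ra, the interleukin 6 receptor chain, had no count in effector memory against 278 CPM in naive, at least 2967-fold lower. Of 10087 genes with at least 5 CPM in either library, 2247 were higher and 1576 lower, 1133 and 524 of them by at least 4-fold.

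The cytotoxic list had 6 of 14 members higher and 1 lower (median log2 ratio 0.96, percentile 99.8). Gzma was 2010.5-fold higher (interval 1219 to 3592) and Prf1, which encodes perforin, 4.56-fold higher (interval 4.37 to 4.76). The neighbouring granzyme genes on chromosome 14, Gzmc (ENSMUSG00000079186.3, chromosome 14, 56231441 to 56234656) and Gzmd (ENSMUSG00000059256.6, chromosome 14, 56129556 to 56132608), were also higher. Gzmc had 3 counts in naive and was 6894-fold higher (interval 2359 to 33432), and Gzmd had none and was at least 2443-fold higher. Ifitm1, a membrane protein of the interferon-induced transmembrane family (ENSMUSG00000025491.14, chromosome 7, 140967221 to 140969825), had no count in naive and 1044 CPM in effector memory, at least 9681-fold higher. Lgals3, which encodes galectin-3, and Emilin2, an extracellular matrix glycoprotein, were at least 3379-fold higher and at least 2875-fold higher. Effector transcription factors had 8 of 12 higher (median log2 ratio 2.89, percentile 100), with Bhlhe40 283-fold higher, Nfil3 197-fold higher and Prdm1, which encodes Blimp-1, 48.6-fold higher.

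All 20 mitosis genes and all 20 DNA replication genes were higher (median log2 ratio 8.86, percentile 100 for mitosis; median log2 ratio 3.29, percentile 100 for replication). Bub1, a spindle checkpoint kinase, was 1195-fold higher (interval 466 to 4386). Cenpf had 2 counts in naive and was 4782-fold higher (interval 1323 to 39487), and Mki67 stood at 1819 CPM. Pclaf, a PCNA-associated factor, had 3 counts in naive and was 3793-fold higher (interval 1298 to 18396). Of 18 glycolysis genes, 17 were higher and none lower (median log2 ratio 3.53, percentile 100). Slc16a3, a lactate exporter, was 364-fold higher (interval 260.5 to 526), Hk2, a hexokinase, 46.8-fold higher (interval 39.5 to 55.9), and Pgk1 stood at 138 and 2929.6 CPM. All 18 cholesterol synthesis genes were higher (median log2 ratio 2.70, percentile 100), with Sqle, squalene epoxidase, 18.5-fold higher. Nuclear oxidative phosphorylation genes had 9 of 24 higher (median log2 ratio 0.87, percentile 99.99) and fatty acid oxidation genes 6 of 16 higher and 1 lower (median log2 ratio 0.67, percentile 99.2).

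The inhibitory receptor and exhaustion list had 9 of 14 higher and 2 lower (median log2 ratio 3.43, percentile 100). Havcr2, which encodes TIM-3, had no count in naive and was at least 1559-fold higher, and Pdcd1 was 302-fold higher (interval 177 to 568). The memory phenotype list had 11 of 15 higher and 1 lower (median log2 ratio 2.86, percentile 100), with Cd44 38.2-fold higher (interval 30.7 to 48.2) and Il12rb2 121-fold higher. Costimulatory receptors had 6 higher and 4 lower of 13 (median log2 ratio 0.69, percentile 98.1). Tnfrsf9, of the TNF receptor family, was 73.6-fold higher, and Slamf6 was 15.4-fold lower. Migration, S100 and annexin genes had 12 of 20 higher (median log2 ratio 2.18, percentile 100), with Anxa2 332-fold higher. The BCL2 family list had 8 higher and 2 lower of 15 (median log2 ratio 1.06, percentile 99.5). Ncr1 had no count in naive or effector memory, so the medians of killer lectin-like receptors and NK cell markers leave it out here. Members measured only through central memory could not be called but entered the medians. Killer lectin-like receptors (4 of 11 higher, median log2 ratio 4.30, percentile 95.5), chemokine genes (5 higher and 2 lower of 11, median log2 ratio 0.69, percentile 71.01), cytokines (median log2 ratio 1.03, percentile 94.4) and NK cell markers (median log2 ratio 2.23, percentile 74.3) lay within the random range. Cytokine receptors also lay within it, with 7 higher and 7 lower of 21, a median log2 ratio of -0.24 and a mean of 0.31; Il2ra, the high-affinity interleukin 2 receptor chain, stood at 0.719 and 456 CPM.

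In the naive and lymphoid homing list, 15 of 16 members were lower in effector memory and none higher (median log2 ratio -3.98, percentile 0). Ccr9, with 3 counts in effector memory, was 3005-fold lower (interval 1028 to 14575), and Klf2, a factor that maintains homing receptor expression, was 70.5-fold lower (interval 61.9 to 80.6). Progenitor and memory transcription factors had 8 lower and 2 higher of 12 (median log2 ratio -2.09, percentile 0), with Tcf7, which encodes TCF-1, 28.1-fold lower and Lef1 7.74-fold lower. Of 15 T cell receptor and CD8 identity genes, 6 were lower (median log2 ratio -0.78, percentile 0.550), Cd8a by 4.57-fold and Cd8b1 by 3.83-fold. Interferon-stimulated genes had 16 of 23 lower and none higher (median log2 ratio -2.04, percentile 0), with Ifit3 165-fold lower (interval 98.3 to 303). Immediate early and heat shock genes had 8 lower and 3 higher of 15 (median log2 ratio -1.25, percentile 0.0400), with Egr2 91.4-fold lower and Ier3 26.2-fold higher. Tissue residency genes had 5 higher and 5 lower of 13 (median log2 ratio -0.67, percentile 2.46), with the integrin Itgae 207-fold lower; the list left the outer range under each other scaling, and its median changed sign at a minimum of 20 CPM. Other genes named by the rule were the potassium channel Kcna2, with 2 counts in effector memory, 2001-fold lower (interval 554 to 16529), Dtx1, 704-fold lower, Ntrk3, at least 534-fold lower, Timp2, 511-fold lower, Vipr1, 247-fold lower, and Slc16a5, 293-fold lower. MHC class I genes (median log2 ratio 0.01, percentile 64.4), mitochondrially encoded genes (median log2 ratio 0.38, percentile 88.98) and ribosomal proteins (median log2 ratio 0.06, percentile 80.6) lay within the random range.

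**Figure D3:**
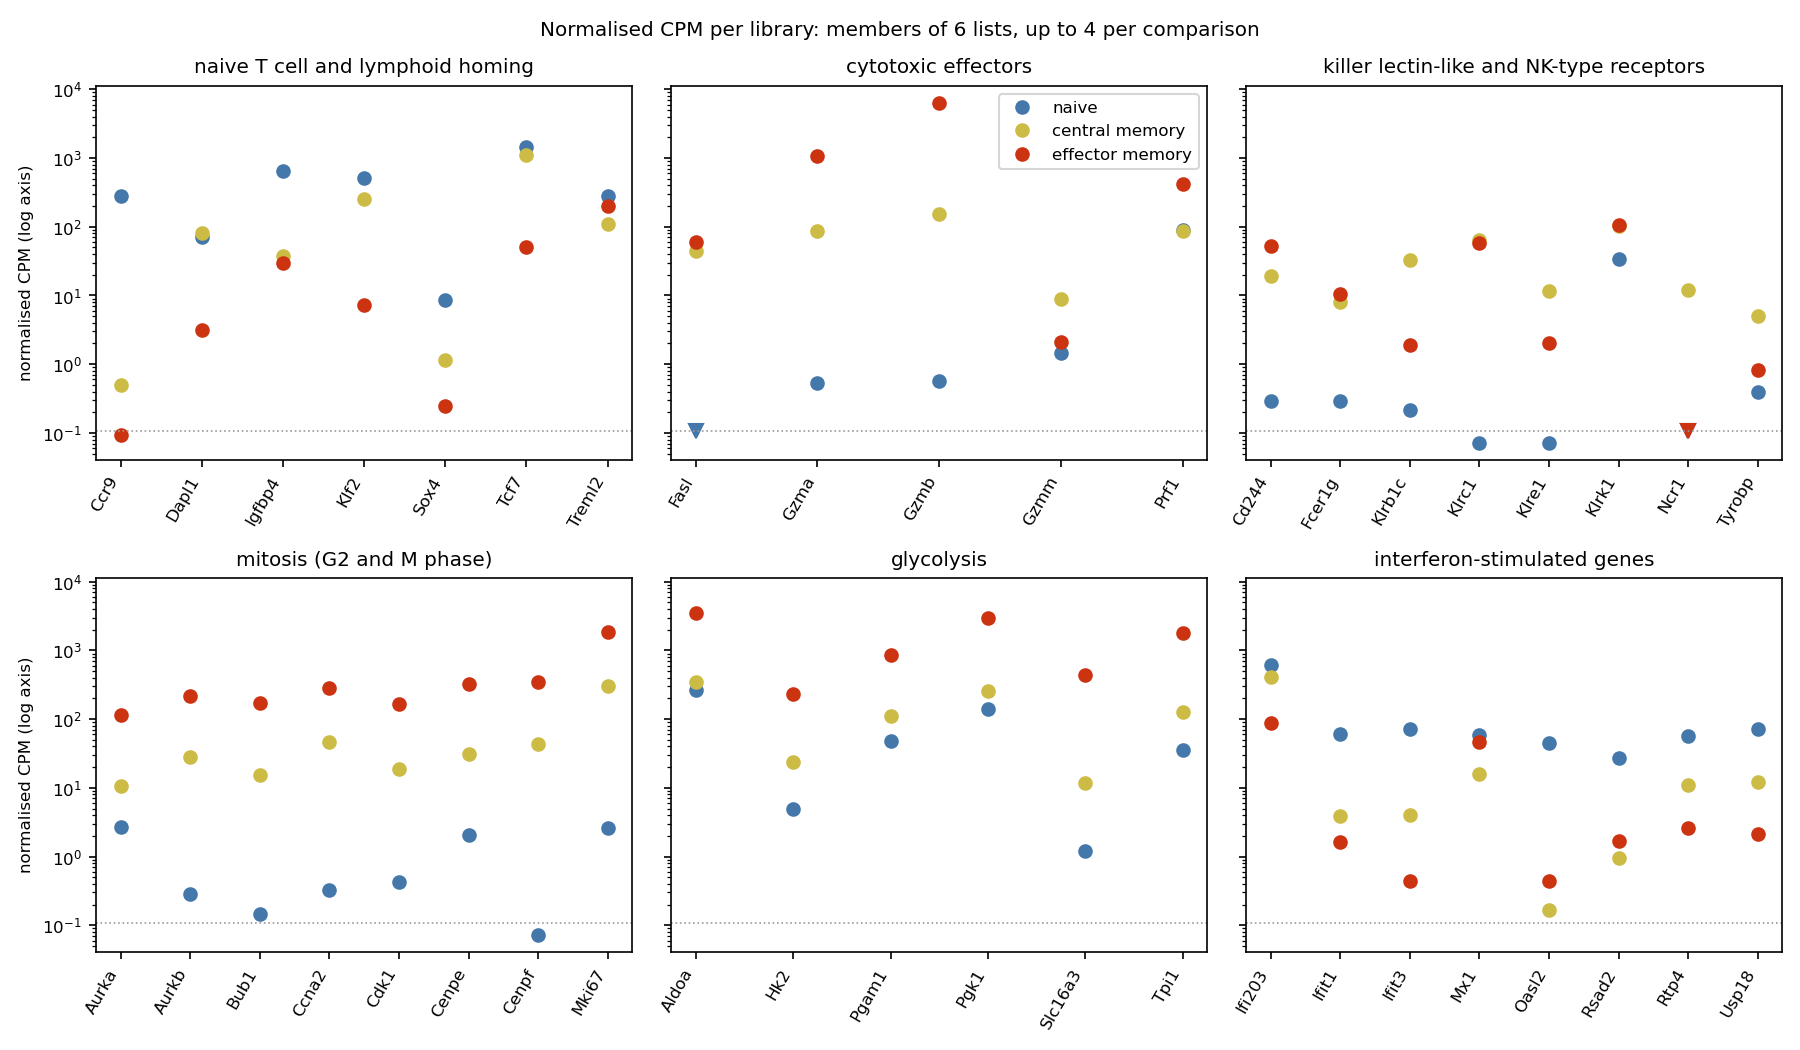
Normalised CPM (log axis) per library for called members of 6 lists, taken from the up to 4 per comparison that lay furthest apart; each point is 1 library, and a triangle marks a count of 0, drawn at the dotted line at 0.108 CPM, the highest of the 3 floors. Mitosis and glycolysis genes are highest in effector memory, and Tcf7 is at 51.5 CPM in effector memory against 1449 in naive; both naive and effector memory are at 0 for Ncr1.

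The third comparison set the memory libraries against each other. In effector memory, 15 of 18 glycolysis genes, all 20 mitosis genes and 17 of 18 cholesterol synthesis genes were higher, and 12 of 16 naive and homing genes were lower. Scd1, a fatty acid desaturase (ENSMUSG00000037071.3, chromosome 19, 44394455 to 44407879), was 732-fold higher (interval 457 to 1256) in effector memory, at 0.475 CPM in central memory and 347 in effector memory. Il6ra had no count in effector memory against 58.8 CPM in central memory, at least 627-fold lower. Of 9975 genes with at least 5 CPM in either library, 1479 were higher and 1273 lower, 635 and 289 of them by at least 4-fold. Both libraries used Trbv12-1 for nearly all Trbv counts.

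Of 18 glycolysis genes, 15 were higher in effector memory (median log2 ratio 2.91, percentile 100), with Slc16a3 37.6-fold higher (interval 34.1 to 41.5), Pgk1 11.5-fold higher (interval 11.3 to 11.8) and Aldoa 10.2-fold higher (interval 10.04 to 10.4). Of 18 cholesterol synthesis genes, 17 were higher (median log2 ratio 2.05, percentile 100), with Idi1 8.84-fold higher (interval 8.05 to 9.73) and Hmgcs1 8.09-fold higher (interval 7.75 to 8.46). Fads2, another fatty acid desaturase, was 293-fold higher (interval 185 to 496). All 20 mitosis genes (median log2 ratio 2.95, percentile 100) and all 20 DNA replication genes (median log2 ratio 1.90, percentile 100) were higher, with Bub1 11.1-fold higher (interval 10.2 to 12.1) and Tk1 5.78-fold higher (interval 5.40 to 6.18). Of 10 mitochondrially encoded genes, 8 were higher (median log2 ratio 1.36, percentile 100), with mt-Nd1 4.24-fold higher. Nuclear oxidative phosphorylation genes had 3 of 24 higher (median log2 ratio 0.52, percentile 99.98), and fatty acid oxidation genes 1 of 16 (median log2 ratio 0.14, percentile 88.2).

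Gzmb was 41.6-fold higher (interval 40.5 to 42.7) in effector memory, although the cytotoxic list lay within the random range, with 4 higher and 3 lower of 14 (median log2 ratio 0.30, percentile 94.7). Effector transcription factors had 5 of 12 higher (median log2 ratio 0.62, percentile 99.5), with Nfil3 16.4-fold higher and Prdm1 9.86-fold higher. Of the interferon-induced transmembrane family, Ifitm1 was 163-fold higher (interval 143 to 186), Ifitm2 (ENSMUSG00000060591.9, chromosome 7, 140954837 to 140955987) 319.7-fold higher (interval 187 to 601) and Ifitm3 (ENSMUSG00000025492.6, chromosome 7, 141009586 to 141010770) 200.4-fold higher (interval 150.1 to 274). Other genes named by the rule were the leukotriene receptor Ltb4r1, 207-fold higher, the collagen prolyl hydroxylase subunit P4ha2, 230.05-fold higher, Endou, with 2 counts in central memory, 464-fold higher (interval 128 to 3840.2), and Mgarp and the histone gene Hist1h1a, at least 374-fold higher and at least 260.2-fold higher. The inhibitory receptor and exhaustion list had 7 higher and 3 lower of 14 (median log2 ratio 0.75, percentile 96.6). Havcr2 was 41.2-fold higher and Tox 11.1-fold lower. Migration, S100 and annexin genes had 8 higher and 2 lower of 20 (median log2 ratio 0.38, percentile 99.00; within the random range at a minimum of 20 CPM).

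Of the naive and homing list, 12 of 16 members were lower in effector memory (median log2 ratio -2.46, percentile 0), with Klf2 34.5-fold lower (interval 30.3 to 39.5) and Dapl1 25.7-fold lower (interval 21.03 to 31.7). Progenitor and memory transcription factors had 8 of 12 lower (median log2 ratio -1.87, percentile 0), with Tcf7 21.2-fold lower (interval 20.2 to 22.3) and Id3 13.01-fold lower (interval 11.04 to 15.4). Chemokine genes had 5 lower and 2 higher of 11 (median log2 ratio -2.03, percentile 0.0100). The chemokine Xcl1 (ENSMUSG00000026573.7, chromosome 1, 164931644 to 164935527) was 128-fold lower (interval 58.4 to 349), Ccl5 12.7-fold lower (interval 11.7 to 13.8), and Cxcr5 had no count in effector memory, at least 164-fold lower. Killer lectin-like and NK-type receptors had 6 lower and 1 higher of 11 (median log2 ratio -1.01, percentile 1.14), with Ncr1 at least 130.04-fold lower and Klrb1c 17.3-fold lower; the list lay within the random range under DESeq2 size factors, upper quartile factors and a minimum of 20 CPM. NK cell markers had 4 lower and 1 higher of 7 (median log2 ratio -2.63, percentile 0.0350), with Cd7 68.6-fold lower and Gzma 12.7-fold higher.

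Cytokine receptors had 6 lower and 4 higher of 21 in effector memory (median log2 ratio -0.60, percentile 0.590), with Il6st 10.4-fold lower and Il2ra 9.39-fold higher. The memory phenotype list had 4 higher and 3 lower of 15, with a median log2 ratio of 0.45 (percentile 99.05) and a mean of -0.12. Other genes lower in effector memory by the naming rule were Vipr1, 98.8-fold lower, Nsg2, 74.7-fold lower, Itgae, 63.3-fold lower, Art2b, 54.7-fold lower, Btbd11, 44.3-fold lower, and Nckap5l, 39.4-fold lower. Interferon-stimulated genes (median log2 ratio -0.42, percentile 4.38), immediate early genes (median log2 ratio 0.48, percentile 92.6), T cell receptor and CD8 identity genes (median log2 ratio -0.51, percentile 5.06), costimulatory receptors (median log2 ratio 0.18, percentile 87.3), cytokines (median log2 ratio -0.10, percentile 41.4), tissue residency genes (median log2 ratio 0.19, percentile 69.3), the BCL2 family (median log2 ratio 0.25, percentile 87.9), MHC class I genes (median log2 ratio -0.27, percentile 30.2) and ribosomal proteins (median log2 ratio -0.17, percentile 54.01) lay within the random range.

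Over the genes that differed at least 4-fold between effector memory and naive, central memory lay between them for most. Choosing genes for the distance between these libraries itself favours any other library lying between them. Genes chosen on another pair were not compared. On a log2 scale with naive at 0 and effector memory at 1, the 1133 genes higher in effector memory had a median central memory position of 0.522 (quartiles 0.299 and 0.679), with 94 genes beyond the naive level and 39 beyond the effector memory level. The 524 genes lower in effector memory had a median position of 0.365 (quartiles 0.174 and 0.690), with 50 and 60 beyond these levels. Of the 1092 genes called higher in central memory than in naive, 820 (75.1%) were also called higher in effector memory, and 92 could not be, since they had less than 5 CPM in both naive and effector memory. Of the 499 called lower, 396 (79.4%) were also called lower. There were 20 genes called in opposite directions. Over the 9598 genes tested in both comparisons, independent lists would share 186 and 81.9 genes. The covariance of both sets of log2(CPM + 1) differences across genes was 1.22, against 0.00262 in simulated unchanged libraries that share a naive control and hold counting error alone, and the correlation was 0.80 against 0.57; genes are not independent replicates. With 1 naive library the control could not be split, so no overlap free of the common control was obtained.

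In the B cell list, 5 of 6 measured members were lower in central memory than in naive (median log2 ratio -3.26, percentile 0.300). In effector memory, 5 were lower and 1 higher than in naive (median log2 ratio -3.79, percentile 0.430). All 6 members reached 5 CPM in naive, against 0 in central memory and 1 in effector memory. Such a filter favours calls of lower, and no member could be called higher in central memory. Cd74, the MHC class II invariant chain, was the highest of them in naive at 19.9 CPM, against 1.84 and 0.313 in the memory libraries, while H2-Ab1 stood at 7.55, 0.893 and 66.9 CPM. Between the memory libraries the B cell list lay within the random range (median log2 ratio -1.04, percentile 4.30). In the list of CD4 and regulatory T cell markers, 5 of 9 members were higher and 2 lower in central memory than in naive (median log2 ratio 2.11, percentile 99.6), and 5 higher and 2 lower in effector memory (median log2 ratio 2.45, percentile 97.98; within the random range under DESeq2 size factors and a minimum of 1 CPM). Those that were higher include Il2ra and Ctla4, receptors also induced on activated CD8+ T cells, and Zbtb7b, while Cd4 did not exceed 2.12 CPM. Between the memory libraries this list (median log2 ratio 1.26, percentile 96.3) lay within the random range, as did the dendritic cell list in all 3 comparisons (median log2 ratio -0.46, percentile 14.1; median log2 ratio 2.11, percentile 65.1; median log2 ratio 1.80, percentile 84.8). No neutrophil or erythroid marker reached 5 CPM. Of the plasma cell, macrophage, gamma delta and NKT, platelet, and stromal and endothelial lists, 1, 3, 2, 2 and 1 members did, too few for a percentile. They were Xbp1 for plasma cells; Axl, Cd68 and Hmox1 for macrophages; Trdv4 and Cd163l1 for gamma delta and NKT cells; Itgb3 and Gp1ba for platelets; and Pecam1 for endothelium. Xbp1 stood at 31.3, 39.5 and 129.6 CPM, Axl at 2.37, 6.11 and 39.7, and Pecam1 at 152, 171 and 53.8.

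Some list medians moved by more than 1.5-fold with the members measured, while the list stayed outside the random range. In central memory against naive, the median of the chemokine list was 4.61 at a minimum of 1 CPM and 5.14 at 20 CPM. That of killer lectin-like receptors was 5.15 at 1 CPM, and that of inhibitory receptor and exhaustion genes 4.87 at 20 CPM. CD4 and regulatory T cell markers stood at 0.97 (percentile 97.7) at 1 CPM, where Cd4 and Foxp3 entered, and NK cell markers at 5.70 with DESeq2 size factors and 5.68 with upper quartile factors, where Tyrobp left. In effector memory against naive, immediate early and heat shock genes stood at -2.34 with total counts, where Klf4 entered and Atf3 left, at -1.85 with upper quartile factors, where Klf4 entered, and at -2.24 at 1 CPM. B cell markers stood at -4.59 with total counts, -4.52 with DESeq2 size factors, -4.59 with upper quartile factors and -4.71 at 1 CPM. At 20 CPM, inhibitory receptor and exhaustion genes stood at 6.39 and CD4 markers at 3.86. Between the memory libraries, NK cell markers stood at -1.89 with DESeq2 size factors and -1.94 with upper quartile factors.

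Across the 30 lists with at least 5 measured members, 61 of 90 list comparisons lay outside the central 95% of matched random lists, where 4.5 would by chance if lists were independent random draws. These percentiles describe the 3 libraries and carry no replicate error. Counts of genes with near-identical copies or pseudogenes, such as the granzyme, Ifitm, Klrc, Oas, histone and MHC families and the glycolysis genes Tpi1, Pgam1 and Gapdh, are uncertain where reads could be split between copies; Gapdh stood at 14.2, 9.18 and 93.4 CPM.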

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

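All tests in this part were chosen only after the result was seen.

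T cell receptor variable segments lay outside the planned comparisons, and their counts in the memory libraries stood out. Trbv12-1 held 99.6% of Trbv counts in central memory and 98.4% in effector memory, against 7.13% in naive. The effective number of Trbv segments was 17.0 in naive, 1.01 in central memory and 1.03 in effector memory. Trav segments stayed more varied, with effective numbers of 44.0, 10.6 and 18.9 in the same order and 65 and 55 segments counted in the memory libraries. Total Trav counts were lower in memory, at 234, 54.8 and 20.01 CPM. The Trav segment with most counts was Trav14n-1 in central memory (479 of 1964, 24.4%) and Trav21-dv12 in effector memory (78 of 640, 12.2%), where Trav14n-1 had 68; in naive they had 8 and 45 counts of 6502.

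Shallow coverage of the locus is argued against, because naive shares predict 4727 counts of other segments in effector memory and 22230.3 in central memory, where 83 and 84 were seen, and so is misassignment between similar segments, since the other Trbv subgroups together were 204-fold lower in effector memory and 241-fold lower in central memory than in naive (477 CPM). A candidate explanation is that most cells of both memory libraries carry 1 receptor, perhaps from a receptor transgene such as OT-I, which pairs Trav14 with Trbv12-1: the Trav14 subgroup led with 45.1% of Trav counts in central memory and held 26.7% in effector memory and 12.9% in naive, at 30.2, 24.7 and 5.35 CPM in naive, central memory and effector memory. Within it, Trav14n-1 (0.288, 13.4 and 2.13 CPM) and Trav14d-1 (0, 4.66 and 0.813 CPM) were higher in memory. In CPM, its other segments with at least 1 CPM in a library, such as Trav14-2 (5.93, 1.03 and 0.219 CPM), were lower. All Trav segments together were lower as well, at 234, 54.8 and 20.01 CPM. As a share of Trav counts, Trav14-1 was not lower, at 4.72%, 8.30% and 5.63%. Trav14-2 had 165 of 6502, 37 of 1964 and 7 of 640 Trav counts. With Trav shares this mixed, 1 shared receptor and a pool expanded from several clones that use Trbv12-1 cannot be told apart, because no junction was counted and the treatment of multi-mapping reads is not stated. Receptor use is confounded with the step from naive to memory in these libraries; the labels give wild-type, untreated mice for all 3 and do not say whether the animals were the same.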

How the results depend on the processing

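All alternatives were planned, and none was added later. Over 621 values of list medians under the alternatives, 591 kept their side of the random range, 13 moved into it, 15 moved out of it and 2 reversed; 9 list settings were not possible because fewer than 5 members were left. No paired analysis was possible because each group has 1 sample, and no library could be left out. Medians moved by more than 1.5-fold in 46 of the 621 values, and 39 of these kept their side. Of the 39, 14 moved with another minimum and 11 with another scaling. In each of these 11 a member near 5 CPM entered or left. The other 14 moved with log2(CPM + 1), which draws ratios of low counts together. With it, mitosis genes went to 4.18 in central and 7.07 in effector memory against naive. In central memory against naive, killer lectin-like receptors went from 6.07 to 3.40 and NK cell markers from 4.79 to 2.80. Chemokine genes between the memory libraries went from -2.03 to -0.60. Counts of called genes, positions and overlaps gave 72 further values, and those not listed here stayed within 1.5 times the reported count or near the reported position. The scalings moved the median log2 ratio of all genes by more than 0.1 in 4 cases: -0.11 for effector memory against naive with total counts, -0.13 and -0.11 for central and effector memory against naive with upper quartile factors, and -0.11 for central memory against naive with DESeq2 size factors. Depth limits genes near 3 counts, whose ratios have wide intervals or are bounds.

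Counts of called genes followed the limits set, since a lower limit admits more genes. With no minimum, 2020 genes were higher and 1540 lower in central memory than in naive, 3566 and 2596 in effector memory than in naive, and 2830 and 1980 in effector memory than in central memory. At a minimum of 1 CPM, 937 were lower in central memory than in naive, and at 20 CPM 544 were higher and 286 lower. At a ratio of at least 4, the counts in the same order of comparisons were 509 and 193, 1133 and 524, and 635 and 289. At a ratio of at least 1.5, they were 2143 and 1051 for central memory against naive, 2649 lower for effector memory against naive, and 2396 and 2528 between the memory libraries. The overlap was 415 genes higher and 161 lower at a ratio of at least 4, and 393 and 236 at 20 CPM. The median position was 0.466 for higher and 0.277 for lower genes at 2-fold, and 0.315 for lower genes at 20 CPM.

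For these list medians, the cause was not tested. Under total counts, tissue residency in effector memory against naive moved into the random range (-0.76), and B cell markers between the memory libraries moved out (-1.62). Under DESeq2 size factors, tissue residency (-0.70) and CD4 and regulatory T cell markers (2.42) in effector memory against naive and killer lectin-like receptors between the memory libraries (-0.59) moved in, and B cell markers moved out (-1.50). Under upper quartile factors, tissue residency (-0.77) and killer lectin-like receptors (-0.64) moved in and B cell markers moved out (-1.55) in the same comparisons. With log2(CPM + 1), tissue residency in effector memory against naive moved in (-0.47). With 10 bins, killer lectin-like receptors in effector memory against naive (4.30) and CD4 markers between the memory libraries (1.26) moved out.

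Other minimum levels change which members are measured. At 1 CPM, fatty acid oxidation in central memory against naive (0.42), and tissue residency (-0.13) and CD4 markers (0.41) in effector memory against naive moved in. Cytokines in central memory against naive (1.18), and killer lectin-like receptors (3.51) and cytokines (1.93) in effector memory against naive moved out. Between the memory libraries, inhibitory receptor and exhaustion genes (0.75), the BCL2 family (0.45), B cell markers (-1.04) and dendritic cell markers (1.80) moved out. At 20 CPM, tissue residency reversed in central memory (0.70) and effector memory (0.69) against naive. Costimulatory receptors in central memory against naive (0.36), and killer lectin-like receptors (-0.16) and migration genes (0.38) between the memory libraries moved in. Cytotoxic effectors (0.44), interferon-stimulated genes (-0.43) and CD4 markers (1.62) between the memory libraries moved out.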

Other observations

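The tests of other cycling cells, of the hypoxia list and of B cells were chosen only after the result was seen, and so were the genes and added lists described here.

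Some genes did not lie between naive and effector memory. Of 9737 genes tested, 171 were called higher in central memory than in both other libraries, and 58 lower than in both. Xcl1 stood at 0.647, 23.95 and 0.188 CPM in naive, central memory and effector memory, and Drc1, a cilium gene, at 2.01, 45.9 and 1.59 CPM. In the same order, Samd3 stood at 0.431, 79.98 and 9.07 CPM and Mxd4, of the MYC and MAX network, at 69.7, 279 and 55.9 CPM. Among the genes lowest in central memory, Gpr55, a lipid receptor, stood at 20.1, 1.03 and 20.9 CPM, Neb at 30.1, 9.66 and 298 CPM and Cxcr4 at 39.3, 13.5 and 40.4 CPM.

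Of the added lists, amino acid transport and one-carbon metabolism genes had a median log2 ratio of 0.36 (percentile 97.4) in central memory against naive, 1.03 (percentile 99.97) in effector memory against naive and 0.88 (percentile 100) between the memory libraries. Nucleolar and ribosome assembly genes stood at -0.15 (percentile 6.20), -0.42 (percentile 11.9) and -0.34 (percentile 18.5) in the same order. Interferon and antiviral receptors and sensors stood at 0.11 (percentile 45.7), -0.51 (percentile 8.04) and -0.25 (percentile 26.98); in central memory against naive their mean was -0.84, of the other sign.

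Mitosis and glycolysis genes were higher in effector memory than in naive. GC content and transcript length are argued against as the whole cause, with medians of 8.69 for mitosis and 3.14 for glycolysis after their trends were removed, against 8.86 and 3.53 before. Cycling B, myeloid, erythroid or CD4 T cells are argued against as the source by 9 lineage genes only. The highest of these, Cd79a, stood at 0.625 CPM where Mki67 stood at 1819 CPM. The 9 leave out H2-Ab1 of the B cell list and Axl of the macrophage list, at 66.9 and 39.7 CPM in effector memory. All 3 measured macrophage markers were called higher there than in naive and than in central memory. The medians of the whole B cell and macrophage lists in effector memory were 0.0625 and 0 CPM. A hypoxia-type response may accompany the glycolysis genes: 15 measured hypoxia genes, P4ha2 among them, had a median log2 ratio of 3.68 against naive (percentile 100) and 2.73 against central memory, and central memory itself stood at 0.62 (percentile 99.5) against naive with 4 of 15 higher, though the list was chosen with such genes already seen. Mitosis genes were also higher in central memory than in naive (median log2 ratio 5.78). For both memory libraries, recent activation, handling of the cells and the memory state itself stay open and were not tested.

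Of 23 measured interferon-stimulated genes, 14 were lower in central memory than in naive and 9 passed in neither direction. In effector memory, 16 were lower than in naive and 7 passed in neither direction. Ifitm1, Ifitm2 and Ifitm3, outside that list, were highest in effector memory. GC content and transcript length are argued against, since the median of central memory against naive was -1.43 after the correction and -1.39 before. B cells in the naive library are argued against, because the interferon list exceeded central memory by 1615 CPM in sum while Cd74 exceeded it by 18.1 CPM. Animal source, handling and the memory state may each contribute, and none of them was tested.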
